A study of Mus musculus with 9 samples.

How the data were processed

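Total RNA of sorted FrII cells (lineage-negative, Sca-1-negative, c-Kit-positive, Mac1 low or positive) from mice aged 2 to 4 months was labelled as biotin cRNA from 5 ug and hybridised to Affymetrix mouse arrays, per the labels' protocols. There were 9 arrays, 3 from wild type, 3 from Sox4-overexpressing leukaemic and 3 from K/L leukaemic mice, and groups were taken from the sample titles. The labels number the samples as from mouse or mice 1 to 3, and say nothing of litters, donors or array batches, so p-values measure the spread between these samples. The authors deposited 1 table of intensity values for 45101 probe sets on a linear scale, with a floor of 8 (log2 value of 3) and a highest value of 22474.538. RMA is named in the submitters' processing notes, but its version and any further step between arrays are not given in the sources used here. No scan dates or batches are used here. Array medians lay between 5.43 and 5.55 on the log2 scale, and between 4.86 and 5.57 percent of probe sets lay at the floor of an array.

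Values were log2 transformed and used with the scaling as deposited. Probe sets were named from a platform annotation of 2016: 34958 probe sets had exactly 1 gene symbol, 932 had several and 9211 had none there. Of the symbols, 34754 were checked through their gene ID in a gene table of assembly GRCm38.p6, used for names, for the chromosome of a gene and for which genes are neighbours, with 0 symbols changed. Probe sets with several symbols or none were left out. Each of 18194 genes was represented by the probe set with the highest mean over all 9 arrays, with probe sets ending in _x_at used if a gene had no other. A gene was tested if at least 3 of the 9 arrays lay above the 40th percentile of all values of that array, which left 12826 genes.

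Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 fit of all 9 arrays with the 3 groups as the only term, which left 6 residual and 3.71 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes of each comparison at a threshold of 0.05. The smallest p of a two-sided permutation test with 3 against 3 arrays is 0.1, so no permutation p is given for single genes. All 3 values of one group lay above all 3 of the other in 58.1 percent of genes for K/L versus wild type, 56.2 percent for Sox4 versus wild type and 51.1 percent for K/L versus Sox4, where chance gives 10 percent. The tests, the samples in each fit, the gene lists, the rule for named genes and all alternatives but those said to be later were chosen before the data were examined.

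Fixed gene lists, 27 in number with 487 members of which 441 were on the arrays with 1 symbol, covered granule, monocyte, stem cell, HoxA and Meis/Pbx, erythroid, megakaryocyte, B, T and NK, mast cell, eosinophil and dendritic cell genes, mitosis, DNA replication, Myc and ribosome biogenesis, interferon, stress, growth factor receptor, transcription factor, Wnt target, Sox, Polycomb, p53 target, BCL2 family and adhesion genes, the sort gate and the sex genes. Of these, 25 were tested against all other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists with at least 4 tested members, and again with an estimated correlation and with fry, which asks if a list's genes move one way on balance and compares them with no other genes. Some members stand in more than 1 list. The named genes are, per comparison, the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups (leaving out uncharacterised transcripts, sex genes and genes with only an _x_at probe set), up to 4 members per list with the smallest p, the 5 largest rises and 5 largest falls shared by both leukaemias, and always Sox4, Cebpa and the sort gate and sex genes. Not all of them are printed.

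On simulated arrays with 50 genes changed at each of 4 sizes, the procedure called 22, 82, 100 and 98 percent of log2 changes of 0.5, 1, 2 and 3 for K/L versus wild type, 46, 78, 96 and 100 percent for Sox4 versus wild type, and 34, 82, 96 and 100 percent for K/L versus Sox4. Of 12626 unchanged genes, 11, 8 and 8 were called in these comparisons, and 2 of 2 shifted lists were called with 0 others in each. Genes were drawn independently there, so the simulation could not show false list calls that come from correlated members. A far smaller share of genes was changed there than passed in the data, where it was 50.6, 47.8 and 28.9 percent in these comparisons. The adjustment depends on that share, so the simulated percentages called do not carry over to the real fits. For the overlap of both comparisons with the same wild type arrays, 100 pairs of unchanged groups were simulated. Replicate arrays were compared in pairs: Pearson r was at least 0.991 except between wild type array 3 and the other wild type arrays (0.979 and 0.977), where 400 and 495 genes lay over 2-fold apart against 18 to 69 in other pairs. Without wild type array 3, the counts of genes past the threshold were 6653, 6343 and 4754 for K/L versus wild type, Sox4 versus wild type and K/L versus Sox4. Principal components 1 and 2 held 55.9 and 32.9 percent of the variance.

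Alternatives were a filter at the 60th percentile and no filter, the mean of all probe sets or the probe set of largest variance per gene, array centring, quantile normalization again, array weights, a trend with robust eBayes, a fit of only the 6 arrays compared, the replicate number as a block, leaving out each array in turn, a 2-fold threshold, an estimated correlation and fry. Markers of other cell types, chromosomes and neighbouring genes were examined in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and R, and figures were drawn with matplotlib 3.10.9.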

Results

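Gene expression was measured with Affymetrix mouse arrays in 9 samples of sorted haematopoietic cells, 3 arrays in each of 3 groups. The sample descriptions name 1 numbered mouse per array, while the titles speak of mice. Sox4 array 3 had signal of both Xist (11.63) and the Y-linked gene Kdm5d (9.01), so whether each array holds 1 mouse is not settled, and n counts arrays. The cells were myeloid progenitors sorted as lineage-negative, Sca-1-negative, c-Kit-positive cells with low or positive Mac1. They are called the FrII fraction in the labels, whose extract protocol also gates on forms of CD45. The source names of the leukaemic samples list those forms, so whether wild type cells passed the same CD45 gate is not settled here. The first group came from wild type C57/BL6 mice, the second from leukaemic mice overexpressing the transcription factor Sox4, and the third from leukaemic K/L mice, in which both alleles of Cebpa are mutated. Cebpa encodes C/EBPα, a transcription factor needed for granulocyte formation. Median intensity per array lay between 43.07 and 46.79 on the linear scale, and the number of arrays limits the precision. Values below are log2 intensities, given as mean ± SD over the 3 arrays of a group (n = 3), and changes are differences of log2 means ± the standard error of the limma fit. The deposited values have a floor of 3 on the log2 scale, so a fall to the floor on all 3 arrays of a group is a lower limit of the true fall.

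The study's question concerned Sox4 in leukaemia with mutant Cebpa, so Sox4 and Cebpa come first. With the probe set of highest mean signal (1433575_at), Sox4 measured 3.87 ± 0.08 in wild type cells, 9.74 ± 0.13 in Sox4 leukaemic cells and 10.67 ± 0.18 in K/L leukaemic cells. The change from wild type was 5.87 ± 0.12 in Sox4 cells (adjusted p = 1.55e-09) and 6.8 ± 0.12 in K/L cells (adjusted p = 5.09e-10). The wild type mean lay below the 40th percentile of its arrays, so the size of these rises rests on little signal on the wild type side. K/L cells lay above Sox4 cells by 0.93 ± 0.12 (adjusted p = 0.000253). Probe sets for Sox4 disagreed with one another, and with the mean of all 8 the change was 1.32 in Sox4 cells and 1.99 in K/L cells. That mean was lowered by 2 probe sets at or near the floor on all arrays and by the probe sets below with no rise past the test. Probe sets 1449370_at and 1419157_at also rose, from 4.55 to 8.16 in Sox4 cells and 8.84 in K/L cells, and from 3.73 to 6.12 and 7.43. The probe set with the next highest mean, 1455867_at, measured 8.33 in wild type, 7.45 in Sox4 and 8.28 in K/L cells, a change of -0.88 in Sox4 cells (adjusted p = 0.00739) and -0.05 in K/L cells (adjusted p = 0.867). Nor was a rise past the test seen with 1419155_a_at, with means of 7.82, 7.34 and 8.27, and for 1419156_at, with 7.63, 7.67 and 8.18. Cebpa (1418982_at) was higher in both leukaemias, at 9.59 ± 0.24 in wild type, 10.58 ± 0.07 in Sox4 and 10.56 ± 0.1 in K/L cells. Its change was 0.99 ± 0.13 in Sox4 cells (adjusted p = 0.000155) and 0.97 ± 0.13 in K/L cells (adjusted p = 0.000168), and the difference between the leukaemias was -0.02 ± 0.13 (adjusted p = 0.933). Kit, a receptor of the sort gate, measured 9.17 ± 0.07, 9.18 ± 0.14 and 9.22 ± 0.13 in wild type, Sox4 and K/L cells.

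**Figure D1:**
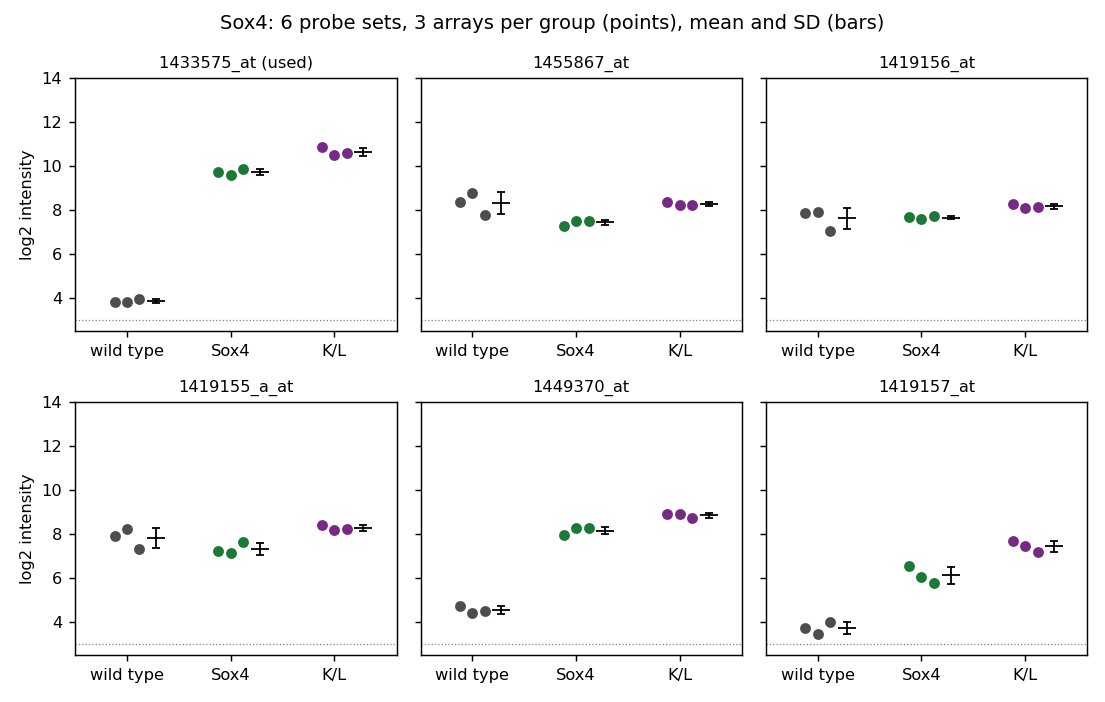
Log2 intensity of the 6 Sox4 probe sets with signal above the floor, with 1 point per array, bars for the mean and SD of 3 arrays per group, and a dotted line at the floor of 3. Probe sets 1433575_at, 1449370_at and 1419157_at lie far lower in wild type than in both leukaemias, whereas 1455867_at, 1419156_at and 1419155_a_at stay between 7.34 and 8.33 in all group means.

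The comparison of K/L with wild type cells asked what distinguishes leukaemic FrII cells with mutant Cebpa from their normal counterparts. Several genes of neutrophil granules and cytoplasm were much lower in K/L cells, while the call for the late neutrophil list as a whole was not held with an estimated correlation (adjusted p = 0.91). S100a8 and S100a9, whose products form the calcium-binding calprotectin complex of neutrophils, went from 12.64 ± 0.18 to 4.64 ± 0.35 and from 13.47 ± 0.28 to 6.24 ± 0.67, changes of -8.01 ± 0.19 and -7.23 ± 0.28 (adjusted p = 1.62e-09 and 5.04e-08). Elane, which encodes neutrophil elastase, changed by -4.04 ± 0.17 (adjusted p = 8.05e-08), and Hdc, which encodes the histamine-forming histidine decarboxylase, by -5.52 ± 0.16 (adjusted p = 5.7e-09). Ctss, which encodes the lysosomal protease cathepsin S, rose from 4.14 ± 0.57 to 10.07 ± 0.21 (change 5.93 ± 0.24, adjusted p = 6.42e-08). Myc rose by 1.06 ± 0.12 from an already high 11.12 ± 0.23 (adjusted p = 6.72e-05).

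Of 12826 genes tested, 6490 passed an adjusted p of 0.05 in limma, 3716 higher and 2774 lower in K/L cells, and 2133 of these differed by at least 2-fold (1203 higher, 930 lower). The largest rises after Sox4 and Ctss were Mndal, a member of the interferon-inducible p200 family (5.9 ± 0.14), and Scin, which encodes an actin-severing protein and lies on chromosome 12 (5.74 ± 0.13). They were followed by the carbonic anhydrase gene Car3 (4.75 ± 0.14, with the same sign in 2 of its 4 probe sets), Bpifc (4.59 ± 0.23) and the leukotriene receptor gene Cysltr1 (4.42 ± 0.18). Cdkn1b, which encodes the cell cycle inhibitor p27 and lies on chromosome 6, rose by 4.24 ± 0.27 and S100a4 by 4.19 ± 0.11. Hspa1b, an inducible heat shock gene, rose by 4.32 ± 0.72 with a wide spread among the K/L arrays (7.86 ± 1.92). The largest falls included Ces1d, which encodes a carboxylesterase (-7.84 ± 0.11), Tmem178 (-7.44 ± 0.15) and Prom1, which encodes the stem cell surface protein prominin (-7.34 ± 0.17). Prkd3, a kinase gene, changed by -7.26 ± 0.14. Similar falls were seen for Slfn4 (-7.23 ± 0.21), Fnbp1l (-6.78 ± 0.1) and the BMP receptor gene Bmpr1a (-6.78 ± 0.12). Bex1 fell by 7.24 to the floor, which is a lower limit. The dimmer group of many of these genes lay below the 40th percentile of its arrays, which is 4.84 to 4.95, so the size of such a change rests on little signal.

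By list, secondary granule and late neutrophil genes had 10 of 17 measured members lower, 2 higher and 5 not past the test, with the same counts adjusted over the list alone (median -1.04). Besides S100a8 and S100a9 the falls included Wfdc21 (-2.25 ± 0.34) and Cd177 (-1.95 ± 0.23). The list test gave adjusted p = 0.0126 with a preset correlation and adjusted p = 0.91 with an estimated correlation. Myc and ribosome biogenesis genes had 12 of 20 higher, 0 lower and 8 not past the test (12 higher and 1 lower adjusted over the list alone, median 0.67), among them Nolc1 (1.35 ± 0.13), Rrp9 (1.07 ± 0.11) and Fbl (0.65 ± 0.08), which act in the nucleolus on ribosomal RNA. Here the test gave adjusted p = 0.0126 and adjusted p = 0.91 with an estimated correlation. Primary granule genes had 8 of 16 members lower and 3 higher in both counts, with adjusted p = 0.0802. Elane, Hdc and Mgst1 (-1.83 ± 0.14, on chromosome 6) fell while the cystatin gene Cst7 rose (1.18 ± 0.1). Monocyte genes had 7 of 15 higher and 3 lower in both counts (adjusted p = 0.429), with rises of Mpeg1 (2.44 ± 0.11) and Cd68 (2.51 ± 0.2) and a fall of the lysozyme gene Lyz2 (-1.51 ± 0.1). Dendritic cell and MHC class II genes had 6 of 10 higher and 1 lower in both counts (adjusted p = 0.255), with H2-DMa at 2.95 ± 0.11 and the dendritic cell regulator Tcf4 at -3.67 ± 0.16. Members of the HoxA and Meis/Pbx list showed 1 call among 11 in both counts, a fall of Myb (-0.6 ± 0.11), and the list gave adjusted p = 0.871. The secondary granule call was lost with the stricter filter, with the mean of all probe sets and without wild type replicate 2, where 0, 1 and 1 lists passed in place of 2. The Myc and ribosome biogenesis call was also lost with the stricter filter. The ratio of 3' to 5' Gapdh control signal, a sign of RNA quality, was 2.68 to 2.91 in wild type and 1.93 to 2.01 in K/L arrays, so that it moved with the same groups as these lists. The same ratio for the actin control overlapped between the groups, at 0.885 to 0.976 in wild type and 0.866 to 0.913 in K/L arrays.

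The comparison of Sox4 leukaemic with wild type cells asked what Sox4 overexpression leukaemia does to the same fraction. Genes higher in Sox4 cells included single ones known from platelets, red cells and myeloid leukaemia. Pf4, the platelet factor 4 gene, rose from 3.56 ± 0.23 to 10.24 ± 0.4 (change 6.69 ± 0.19, adjusted p = 1.2e-08), and Car2, a carbonic anhydrase gene of red cells, from 5.01 ± 0.1 to 9.42 ± 0.05 (4.41 ± 0.21, adjusted p = 2.2e-07). Meis1, a homeobox cofactor known from myeloid leukaemia, rose from 4.21 ± 0.23 to 7.68 ± 0.14 (3.47 ± 0.13, adjusted p = 5.2e-08), its partner Hoxa9 by 1.71 ± 0.11 (adjusted p = 1.24e-06) and the receptor tyrosine kinase gene Flt3 by 3.24 ± 0.2 (adjusted p = 1.09e-06). The survival gene Bcl2 rose by 2.11 ± 0.14 (adjusted p = 2.04e-06), and the p53 target genes Pmaip1, Perp and Trp53inp1 changed by -3.31 ± 0.13, -3.82 ± 0.23 and -2.92 ± 0.13 (adjusted p = 6.28e-08, 1.09e-06 and 1.18e-07). The p53 target list as a whole had 4 of 15 members higher and 5 lower in both counts, with a median of 0.05 (adjusted p = 0.489).

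In this comparison 6135 of 12826 genes passed the limma test, 3427 higher and 2708 lower in Sox4 cells, and 1997 of them changed by at least 2-fold (1180 higher, 817 lower). Large rises besides Pf4 were those of Ctss (6.04 ± 0.24), Mndal (5.77 ± 0.14) and Cd27, a TNF receptor family gene (5.61 ± 0.2). Cavin2, which shapes caveolae, rose by 4.88 ± 0.23. Further rises were those of Tceal8 (4.74 ± 0.24), Ifi209, a relative of Mndal (4.73 ± 0.43), Ica1 (4.5 ± 0.18) and Fyb, an adaptor gene of blood cells (4.48 ± 0.36). Large falls were those of Ces1d (-7.76 ± 0.11), Hao1, a peroxisomal oxidase gene (-7.12 ± 0.27), Bmpr1a (-6.49 ± 0.12) and Slfn4 (-6.29 ± 0.21). They were followed by Glyat (-6.05 ± 0.09), Ct55 (-5.98 ± 0.45), Aspa (-5.96 ± 0.33) and Olfm4 (-5.92 ± 0.12). Ugt8a fell by 6.07 and Klhl41 fell by 5.74, in both cases to the floor and so as lower limits.

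Of the gene lists, 9 were higher and 0 lower in Sox4 cells, and 0 of the 9 calls held with an estimated correlation. Monocyte genes rose in 12 of 15 members and fell in 2, also adjusted over the list alone (median 1.62). Tested as a list, they gave adjusted p = 0.00135, and adjusted p = 0.208 with an estimated correlation. Csf1r, the M-CSF receptor gene, rose by 1.62 ± 0.1 and Mpeg1 by 3.24 ± 0.11, while Adgre1, which encodes the macrophage antigen F4/80, changed by -3.22 ± 0.13. HoxA and Meis/Pbx genes rose in 8 of 11 and fell in 1 in both counts (median 1.57), Hoxa3 by 2.07 ± 0.11. As a set they gave adjusted p = 0.00135, and adjusted p = 0.0962 with an estimated correlation. Erythroid genes rose in 10 of 18 and fell in 1 in both counts (median 1.24), including Car1 (3.83 ± 0.15), the water channel gene Aqp1 (2.68 ± 0.09) and Tfr2 (1.99 ± 0.11). Against all other genes, the list gave adjusted p = 0.00147, and adjusted p = 0.0962 with an estimated correlation. Dendritic cell and MHC class II genes rose in 7 of 10 and fell in 0 (8 and 1 adjusted over the list alone, median 1.18), with H2-DMa at 4.06 ± 0.11 and H2-Ab1 at 2.73 ± 0.24. The camera test gave adjusted p = 0.00479, and adjusted p = 0.316 with an estimated correlation. Interferon-stimulated genes rose in 12 of 20 and fell in 0 (13 and 0 adjusted over the list alone, median 0.65), among them Oasl2 (3.01 ± 0.36) and Oas1a (2.65 ± 0.31). Tested as a list, they gave adjusted p = 0.00147, and adjusted p = 0.47 with an estimated correlation.

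Lists of cell growth and division were among those 9. Mitosis genes rose in 13 of 23 and fell in 0 in both counts (median 0.34), Mki67 by 1.35 ± 0.16, Aurkb by 1.14 ± 0.12 and Ccna2 by 0.9 ± 0.09. As a set they gave adjusted p = 0.00479, and adjusted p = 0.281 with an estimated correlation. DNA replication genes rose in 13 of 24 and fell in 0 (14 and 0 adjusted over the list alone, median 0.39), including Cdt1 (0.97 ± 0.14) and Mcm5 (0.77 ± 0.09), which license replication origins. Against all other genes, the list gave adjusted p = 0.00839, and adjusted p = 0.208 with an estimated correlation. Myc and ribosome biogenesis genes rose in 14 of 20 and fell in 2 in both counts (median 0.61), with the spermidine synthase gene Srm at 1.63 ± 0.18 and Nolc1 at 1.17 ± 0.13. The camera test gave adjusted p = 0.00147, and adjusted p = 0.316 with an estimated correlation. Growth factor receptor genes rose in 9 of 17 and fell in 1 in both counts (median 0.7), with the interleukin receptor genes Il1r1 (2.54 ± 0.1, with the same sign in 1 of its 2 probe sets) and Csf2rb2 (1.93 ± 0.12). Tested as a list, they gave adjusted p = 0.00479, and adjusted p = 0.46 with an estimated correlation. Stem and early progenitor genes rose in 11 of 19 and fell in 4 in both counts, with adjusted p = 0.0868, and included Tek, which encodes the angiopoietin receptor (2.7 ± 0.18). The late neutrophil list held 9 rises and 5 falls among 17 in both counts (adjusted p = 0.663). The lactoferrin gene Ltf rose by 2.33 ± 0.17 while S100a8 and S100a9 changed by -2.19 ± 0.19 and -2.62 ± 0.28. Primary granule genes had 4 rises and 4 falls among 16 in both counts (adjusted p = 0.576), with rises of Ctsc (1.61 ± 0.09) and Fcnb (2.83 ± 0.19). The Gapdh ratio of 3' to 5' signal was 2.22 to 2.44 in Sox4 arrays against 2.68 to 2.91 in wild type, moving with the same groups. The actin ratio overlapped, at 0.881 to 0.915 in Sox4 and 0.885 to 0.976 in wild type arrays.

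**Figure D2:**
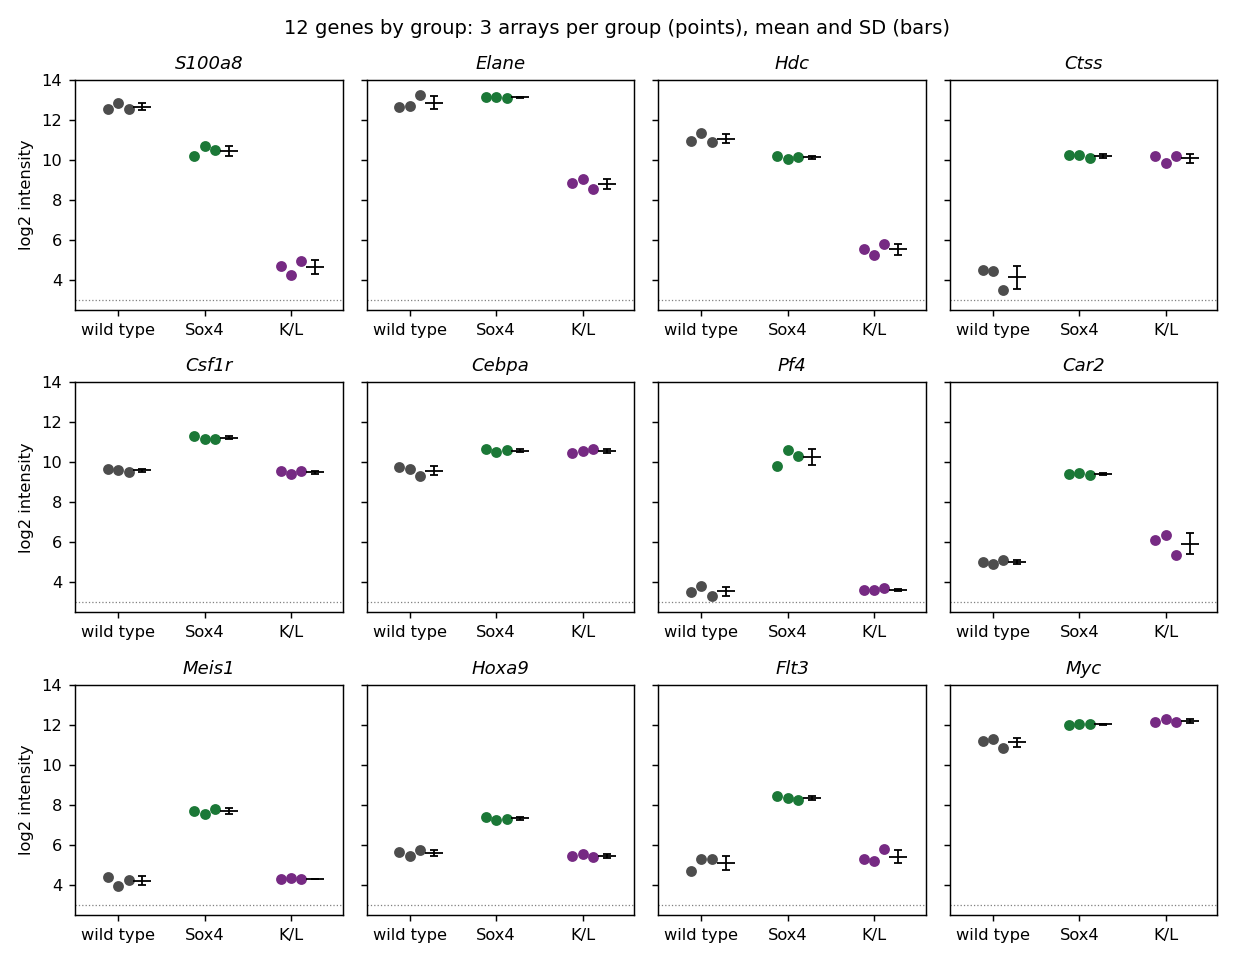
Log2 intensity of 12 named genes in the 3 groups, with 1 point per array, bars for the mean and SD of 3 arrays, and a dotted line at the floor of 3. S100a8, Elane and Hdc are lowest in K/L cells, Ctss is high in both leukaemias, Cebpa and Myc lie about 1 log2 unit above wild type in both, and Pf4, Car2, Meis1, Hoxa9, Flt3 and Csf1r are highest in Sox4 cells.

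Setting the leukaemias against each other asked where the K/L and Sox4 leukaemic cells differ. Whether the 3 arrays of a group come from separate leukaemias is not known here. Differences are therefore between these arrays and are not shown to follow from genotype. Primary granule genes and HoxA and Meis/Pbx genes were lower in K/L cells as lists, each with adjusted p = 0.0218 with an estimated correlation. Elane measured 8.8 ± 0.24 in K/L and 13.12 ± 0.01 in Sox4 cells, a change of -4.32 ± 0.17 (adjusted p = 9.99e-08), and S100a8 changed by -5.81 ± 0.19 (adjusted p = 2.47e-08). Meis1 changed by -3.39 ± 0.13 and Hoxa9 by -1.87 ± 0.11 (adjusted p = 8.13e-08 and 9.14e-07), and Pf4 by -6.61 ± 0.19 (adjusted p = 1.13e-08). Higher in K/L cells were Perp, a p53 target of cell adhesion, by 4.37 ± 0.23 (adjusted p = 6.07e-07), and Scin by 4.88 ± 0.13 (adjusted p = 6.87e-09).

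Here 3702 genes passed, 1905 higher and 1797 lower in K/L cells, and 1165 of them differed by at least 2-fold, with 466 higher and 699 lower. With each array centred on its median the split was 2546 higher and 1456 lower, so the balance of directions depends on the scaling. Other large rises were Ripk4, a kinase gene of epithelia (5.65 ± 0.16), Morc1 (5.39 ± 0.48) and Islr (5.09 ± 0.17). Smaller ones were those of Hpse2 (4.78 ± 0.35), Olfm4, a glycoprotein gene of neutrophil granules (4.62 ± 0.12), and Mzb1 (4.51 ± 0.14). Large falls were Ifitm3, an interferon-induced antiviral gene (-7.13 ± 0.45), the Krüppel-like factor gene Klf9 (-6.85 ± 0.18) and Prom1 (-6.41 ± 0.17). They also included Ppic (-6.02 ± 0.47), the imprinted antisense transcript Kcnq1ot1 (-5.88 ± 0.13), Ctla2a (-5.84 ± 0.34) and Prkd3 (-5.84 ± 0.14). App, the amyloid precursor gene, changed by -5.76 ± 0.25, with the same sign in 2 of its 4 probe sets. Genes of chromosomes 6 and 12 were higher as a set in K/L cells. Over the 381 and 270 genes with a mean log2 value above 7, the median of each K/L array lay 0.391 to 0.419 above the mean of the 6 wild type and Sox4 arrays. Without these chromosomes 3091 genes passed, 1412 higher and 1679 lower, an alternative chosen after seeing the data.

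Of the lists, 11 were lower in K/L than in Sox4 cells and 1 was higher. HoxA and Meis/Pbx genes were lower in 8 of 11 and higher in 0 (9 and 0 adjusted over the list alone, median -1.5). As a set they gave adjusted p = 7.91e-07, and adjusted p = 0.0218 with an estimated correlation. Primary granule genes were lower in 8 of 16 and higher in 0 in both counts (median -0.39). Against all other genes, the list gave adjusted p = 3.85e-06, and adjusted p = 0.0218 with an estimated correlation. Erythroid genes were lower in 9 of 18 and higher in 2 in both counts (median -0.44). The camera test gave adjusted p = 0.000499, and adjusted p = 0.0494 with an estimated correlation. These 3 calls held with an estimated correlation. Besides Elane, the primary granule members that fell included Hdc (-4.59 ± 0.16), Fcnb (-2.98 ± 0.19) and Igsf6 (-1.03 ± 0.09). Erythroid falls included Car1 (-3.83 ± 0.15), Car2 (-3.48 ± 0.21), Aqp1 (-2.55 ± 0.09, on chromosome 6 like Hoxa3 and Hoxa9) and the blood stem cell factor Tal1 (-2.59 ± 0.17). Late neutrophil genes were lower in 13 of 17 members and higher in 2 (14 and 2 adjusted over the list alone, median -1.96), with Ltf at -2.41 ± 0.17 and Wfdc21 at -4.72 ± 0.34. Tested as a list, they gave adjusted p = 1.51e-06, and adjusted p = 0.197 with an estimated correlation. Megakaryocyte genes were lower in 8 of 13 and higher in 1 (10 and 1 adjusted over the list alone, median -0.94), with the thrombin receptor gene F2r at -5.1 ± 0.21 and Vwf at -3.48 ± 0.33. As a set they gave adjusted p = 8.12e-05, and adjusted p = 0.0936 with an estimated correlation. Monocyte genes were lower in 9 of 15 and higher in 2 in both counts (median -0.76), Csf1r by -1.72 ± 0.1 and Ccr2 by -2.12 ± 0.16, against a rise of Adgre1 (2.81 ± 0.13). Against all other genes, the list gave adjusted p = 0.00228, and adjusted p = 0.152 with an estimated correlation.

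Mitosis genes were lower in 17 of 23 and higher in 0 (19 and 0 adjusted over the list alone, median -0.41), by sizes such as -0.54 ± 0.08 for the kinesin gene Kif11 and -0.71 ± 0.12 for Cenpe. The camera test gave adjusted p = 3.72e-06, and adjusted p = 0.0611 with an estimated correlation. Interferon-stimulated genes were lower in 8 of 20 and higher in 0 (9 and 1 adjusted over the list alone, median -0.53), led by Ifit2 (-2.23 ± 0.18). Tested as a list, they gave adjusted p = 0.00347, and adjusted p = 0.485 with an estimated correlation. Stem and early progenitor genes were lower in 9 of 19 and higher in 2 (9 and 3 adjusted over the list alone, median -0.59), with Flt3 at -2.92 ± 0.2 and Tek at -2.58 ± 0.18. As a set they gave adjusted p = 0.0137, and adjusted p = 0.152 with an estimated correlation. Dendritic cell and MHC class II genes were lower in 4 of 10 and higher in 1 (5 and 1 adjusted over the list alone, median -0.55), where Tcf4 changed by -4.82 ± 0.16 and the integrin gene Itgax by 2.89 ± 0.2. Against all other genes, the list gave adjusted p = 0.0179, and adjusted p = 0.315 with an estimated correlation. Growth factor receptor genes were lower in 6 of 17 and higher in 3 (7 and 4 adjusted over the list alone, median -0.24), with Il1r1 at -2.16 ± 0.1 (same sign in 1 of 2 probe sets). The camera test gave adjusted p = 0.0228, and adjusted p = 0.485 with an estimated correlation. The p53 target genes were higher in 6 of 15 and lower in 0 in both counts (median 0.22), with Pmaip1 at 2.47 ± 0.13, Trp53inp1 at 1.94 ± 0.13 and Zmat3 at 0.51 ± 0.09. Tested as a list, they gave adjusted p = 0.0179, and adjusted p = 0.152 with an estimated correlation. The stem cell call was lost with the stricter filter and in a fit of the 6 arrays alone, and the dendritic cell call without a filter. Gapdh 3' to 5' ratios of 1.93 to 2.01 in K/L and 2.22 to 2.44 in Sox4 arrays moved with these groups too. Actin ratios overlapped, at 0.866 to 0.913 in K/L and 0.881 to 0.915 in Sox4 arrays.

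**Figure D3:**
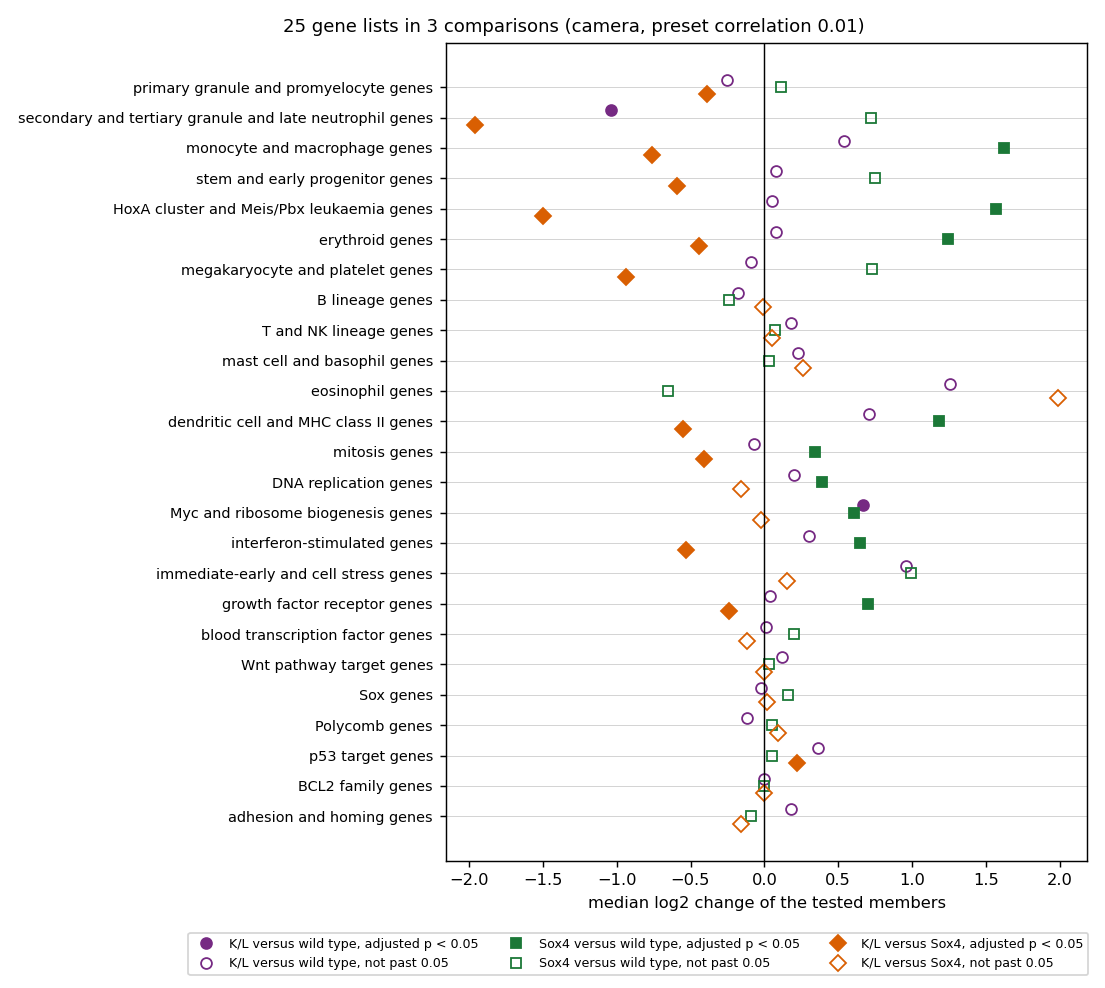
Median log2 change of the tested members of 25 gene lists in the 3 comparisons, with filled symbols where the list test gave an adjusted p under 0.05 with a preset correlation of 0.01. K/L versus wild type has 2 filled symbols, Sox4 versus wild type 9 and K/L versus Sox4 12, of which 11 lie left of 0.

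Both leukaemias departed from wild type in many of the same genes. Past the test in the same direction were 4243 genes, 2407 higher and 1836 lower in both, where independent lists of these lengths would share 993 and 586. Rises shared by both included Ctss, Sox4, Mndal, Hspa1b and Ahnak, a large scaffold protein gene (3.96 ± 0.15 in K/L and 3.93 ± 0.15 in Sox4 cells). Falls shared by both were led by Ces1d, Bmpr1a, Hao1 (-6.37 ± 0.27 in K/L cells), Slfn4 and Ugt8a, which measured 9.07 ± 0.3 in wild type and the floor of 3 in all 6 leukaemic arrays. Of the shared genes, 1103 also differed between the leukaemias, and 275 genes went in opposite directions. Across genes, which are not independent replicates, the changes from wild type correlated with Pearson r = 0.665 and Spearman rho = 0.69. Simulations of all 9 arrays without group differences, in which 2 groups shared 3 simulated wild type arrays, gave a mean r of 0.5 over 100 simulations. The covariance was 0.535 against 0.0157 simulated, a difference of 0.52. Shared calls were 0 in these simulations, but no gene was changed there and genes were drawn independently. The 0 therefore does not measure how many shared calls come from the real wild type arrays. The 3 wild type arrays cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls.

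**Figure D4:**
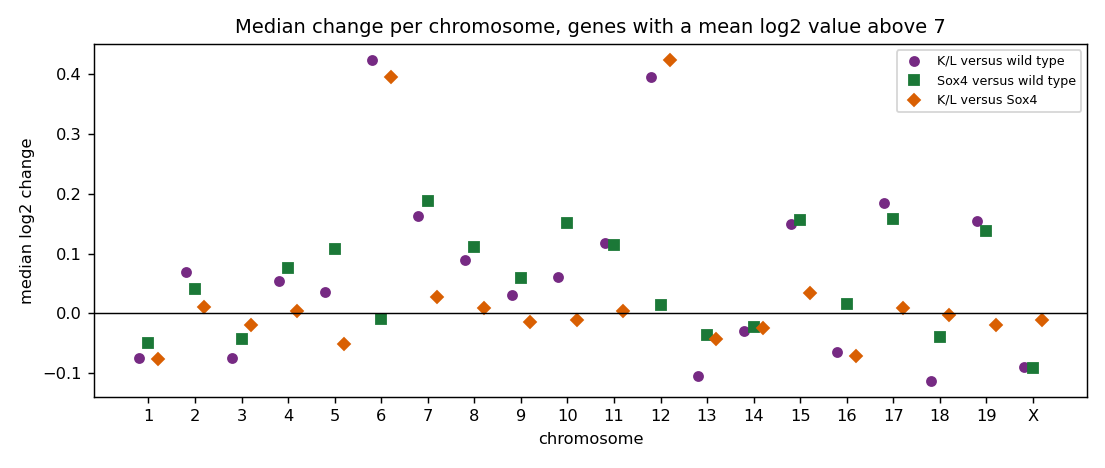
Median log2 change of genes with a mean log2 value above 7 on each of 20 chromosomes (horizontal axis) in the 3 comparisons (symbols). Chromosomes 6 and 12 stand apart in both K/L comparisons, while the other chromosomes lie between -0.077 and 0.034 in K/L versus Sox4.

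B lineage genes had 3 higher and 1 lower of 8 in K/L versus wild type (3 and 2 adjusted over the list alone, adjusted p = 0.909). They had 2 and 2 in Sox4 versus wild type (2 and 4 adjusted over the list alone, adjusted p = 0.685) and 2 and 2 between the leukaemias in both counts (adjusted p = 0.835). Cd79b, a signalling chain of the B cell receptor, rose by 1.38 ± 0.11 in K/L and 1.9 ± 0.11 in Sox4 cells. T and NK lineage genes had 2 higher and 1 lower of 11 in K/L versus wild type in both counts (adjusted p = 0.819). They had 3 and 1 in Sox4 versus wild type (2 and 1 adjusted over the list alone, adjusted p = 0.737), and 1 and 0 between the leukaemias in both counts (adjusted p = 0.835). Bcl11b, a T lineage transcription factor gene, changed by -4.58 ± 0.25 and -4.72 ± 0.25 from 9.07 ± 0.54 in wild type. Megakaryocyte genes had 0 higher and 5 lower of 13 in K/L versus wild type (0 and 4 adjusted over the list alone, adjusted p = 0.164), among them F2r (-4.19 ± 0.21) and Thbs1 (-2.82 ± 0.22). In Sox4 versus wild type 9 were higher and 2 lower in both counts (adjusted p = 0.148). Blood transcription factor genes had 10 higher and 9 lower of 30 in K/L versus wild type (adjusted p = 0.819), 14 and 8 in Sox4 versus wild type (adjusted p = 0.396) and 3 and 9 between the leukaemias (adjusted p = 0.0638), in each case also adjusted over the list alone. Ets1 changed by -2.28 ± 0.13 in K/L and -2.44 ± 0.13 in Sox4 cells, Gfi1b rose by 2.01 ± 0.17 and 2.02 ± 0.17, and Klf4, a monocyte factor, rose by 3.48 ± 0.3 in Sox4 cells.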

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

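The genes named in this part were chosen after their values were seen, while the list tests between the leukaemias and the split counts were fixed beforehand. Compared with wild type, 275 genes changed in opposite directions in the K/L and Sox4 cells in the limma test, 120 of them higher in K/L cells and 155 lower. A difference between the leukaemias follows from this choice of genes and is no separate test. Ctnnd1, which encodes the junction protein p120 catenin, changed by -2.97 in K/L and 2.78 in Sox4 cells, a difference of -5.75. Ripk4 changed by 2.43 and -3.22, a difference of 5.65, and Morc1, known from the male germ line, by 3.17 and -2.22, a difference of 5.39. Wfdc21, a secreted protein gene of neutrophils, changed by -2.25 and 2.47, a difference of -4.72.

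Among the gene lists, those whose difference between the leukaemias also held with an estimated correlation were the primary granule genes (median difference -0.39), the HoxA and Meis/Pbx genes (-1.5) and the erythroid genes (-0.44), each lower in K/L than in Sox4 cells. In fits of 6 arrays, K/L versus wild type gave 5866 genes, Sox4 versus wild type 5498 and K/L versus Sox4 4797, and in each comparison 1 of the 10 splits, the real one, gave as many, with 0 genes as the highest of the others. These 10 splits are too few for a share under 0.05.

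Xist, the RNA of the inactive X chromosome, belongs to the sex genes, which no gene list test used, and stood out in part of the Sox4 arrays. It measured 12.1 on Sox4 array 1 and 11.63 on Sox4 array 3, against 4.68 on Sox4 array 2 and 4.6 to 5.34 on the wild type and K/L arrays. Kdm5d, a gene of the Y chromosome, measured 10.6 to 10.86 on wild type and 9.6 to 9.93 on K/L arrays. On Sox4 arrays 1, 2 and 3 it measured 4.14, 9.91 and 9.01. Array 3 thus had signal of both, with linear intensities of 72.2 percent of array 1 for Xist and 53.6, 56.3 and 62.4 percent of array 2 for Kdm5d, Uty and Eif2s3y. By these genes, sex was not balanced between the Sox4 arrays and the others, so both Sox4 comparisons may hold differences of sex.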

How the results depend on the processing

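The setting without chromosomes 6 and 12 and the other Sox4 probe set were chosen only after the results were seen. Sox4 depends on its probe set: with the mean of all probe sets the change was 1.99 in K/L and 1.32 in Sox4 cells. That mean was lowered by 2 probe sets at or near the floor and by those with no rise past the test. With 1455867_at the limma change was -0.05 in K/L cells (adjusted p = 0.867) and -0.88 in Sox4 cells (adjusted p = 0.00739). The cause of the disagreement between probe sets was not decided by the tests run. Counts of genes past the threshold stayed within 1.5 times under all settings except the 2-fold threshold, which gave 2133 for K/L versus wild type, 1997 for Sox4 versus wild type and 1165 for K/L versus Sox4. With each array centred on its median, 4440 genes were higher and 2273 lower in K/L versus wild type, and 2667 and 1586 in both leukaemias. With 1 array left out in turn the counts ranged over 5595 to 6653, 5224 to 6343 and 2786 to 4754, and genes shared by both leukaemias over 3706 to 4391. Of 506 alternative values for 23 list results, 479 kept the call and 27 lost it, 20 of these with an estimated correlation. For K/L versus wild type, where 2 lists passed, 4 passed without a filter, 0 with the stricter filter, 1 with the mean of all probe sets, 0 with an estimated correlation, 17 with fry, and 1 to 3 with 1 array left out, where the 1 came without wild type replicate 2. For Sox4 versus wild type 0 lists passed with an estimated correlation and 18 with fry, and for K/L versus Sox4 3 passed with an estimated correlation. Fry tests another question, and for the other settings the cause was not tested. The correlation of the 2 fold changes was 0.679 with the stricter filter, 0.675 with the mean of all probe sets, 0.692 with the probe set of largest variance, 0.655 with array weights, 0.677 without chromosomes 6 and 12, and 0.651 to 0.682 with 1 array left out. Of 325 results for named genes other than Sox4 and Cebpa, under the alternatives fixed beforehand, 6052 of 6135 alternative values kept direction and call, 83 lost the call, 0 reversed, and 18 results were affected. The stricter filter left 290 of these tested. Most named genes were chosen from the same data for large changes or small p-values, so the values kept are no separate support. Array numbers did not pair the arrays: same-numbered arrays correlated at -0.024 to 0.082 in their deviations, others at -0.05 to 0.053, and 3 of 9 arrays correlated best with their own number. A replicate block gave 6369, 5999 and 3503 genes. Dim genes are the limit of depth here, since a change of a group near the floor is imprecise and a fall to the floor on all arrays of a group is a lower limit.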

Other observations

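The tests on chromosomes 6 and 12, Sox4 probe sets, single faulty probe sets and neighbouring genes were chosen only after the result was seen, while the marker tests for other cell types were not. Eosinophil and mast cell genes gave no list call in any comparison. Of 6 eosinophil genes, 3 were higher and 1 lower in K/L versus wild type (adjusted p = 0.292), 2 and 3 in Sox4 versus wild type (adjusted p = 0.737), and 4 and 2 in K/L versus Sox4 (adjusted p = 0.23), in each case also adjusted over the list alone. Il5ra, the interleukin-5 receptor gene on chromosome 6, rose by 2.15 ± 0.23 in K/L cells and was 3.96 ± 0.23 above Sox4 cells. Epx, which encodes eosinophil peroxidase, rose by 3.12 ± 0.16 in Sox4 cells, and the granule protein gene Prg2 rose in both (2.23 ± 0.25 in K/L, 4.44 ± 0.25 in Sox4 cells). Of 8 mast cell and basophil genes, 3 were higher and 3 lower in K/L versus wild type (4 and 3 adjusted over the list alone, adjusted p = 0.819), 2 and 3 in Sox4 versus wild type (adjusted p = 0.737) and 4 and 3 between the leukaemias (adjusted p = 0.835), the last 2 also adjusted over the list alone. The mast cell carboxypeptidase gene Cpa3 rose by 3.47 ± 0.55 in K/L cells from a spread-out 8.46 ± 1.42 in wild type, and Ms4a2, a chain of the IgE receptor, rose by 2.34 ± 0.2 in Sox4 cells and changed by -1.26 ± 0.2 in K/L cells.

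Stress genes gave no list call in any comparison. Of 16 immediate-early and cell stress genes, 10 rose and 2 fell in K/L (adjusted p = 0.0802) and in Sox4 cells (adjusted p = 0.0633), also adjusted over the list alone, with 2 higher and 2 lower between them (adjusted p = 0.835). Fosb rose by 3.72 ± 0.54 in K/L cells and Egr1 by 3.86 ± 0.65 in Sox4 cells, while Gadd45a changed by -1.25 ± 0.1 and -1.16 ± 0.1. Adhesion genes had 7 rises and 4 falls of 16 in K/L (7 and 5 adjusted over the list alone, adjusted p = 0.984), 5 and 3 in Sox4 cells (5 and 5 adjusted over the list alone, adjusted p = 0.84) and 3 and 5 between them (4 and 7 adjusted over the list alone, adjusted p = 0.509). Vcam1, an adhesion receptor gene, changed by -5.0 ± 0.2 in K/L and -3.76 ± 0.2 in Sox4 cells, and the selectin ligand gene Selplg rose by 1.87 ± 0.25 and 2.93 ± 0.25. Polycomb genes moved both ways (4 and 4, 7 and 6, and 3 and 4 of 16 higher and lower in K/L versus wild type, Sox4 versus wild type and K/L versus Sox4, adjusted p = 0.819, 0.95 and 0.815), with Cbx2 at -1.97 ± 0.17 in K/L cells and Bmi1 at -0.89 ± 0.09 in Sox4 cells. BCL2 family genes had 4 and 1, 4 and 2, and 3 and 2 of 11 (adjusted p = 0.819, 0.737 and 0.913), and both counts were the same adjusted over the list alone here and for Polycomb genes. Bak1, a pro-apoptotic gene, rose by 1.05 ± 0.17 in K/L and 1.02 ± 0.17 in Sox4 cells. Wnt target genes had 4 and 1, 4 and 1, and 1 and 2 of 10 (the last 1 and 3 adjusted over the list alone, adjusted p = 0.819, 0.543 and 0.815). Rnf43, a Wnt feedback gene, rose by 3.85 ± 0.19 in K/L cells, and Ccnd1 by 1.56 ± 0.13 in Sox4 cells. Sox genes had 3 and 2, 3 and 1, and 1 and 2 of 7 in both counts (adjusted p = 0.871, 0.319 and 0.67). Sox12 rose by 2.45 ± 0.17 in Sox4 cells. p53 target genes had 7 and 5 of 15 in K/L versus wild type (8 and 5 adjusted over the list alone, adjusted p = 0.819). Of the sort gate genes, Itgam, the Mac1 gene, was dim, at 4.91 ± 0.13 in wild type, 4.2 ± 0.25 in Sox4 and 3.83 ± 0.17 in K/L cells. Ptprc, the CD45 gene, changed by -0.44 ± 0.1 in K/L and -0.49 ± 0.1 in Sox4 cells, a call lost with the probe set of largest variance. Median, mean and list test differed in sign, without a call, for the stem cell, HoxA and Meis/Pbx, B, T and NK, mast cell, mitosis, transcription factor, Sox and adhesion lists in K/L versus wild type. The same held for the B, T and NK, mast cell, eosinophil, p53 target and adhesion lists in Sox4 versus wild type, and for the B, mast cell, Sox, Polycomb and BCL2 family lists in K/L versus Sox4.

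Chromosomes 6 and 12 stood out in K/L arrays. Bright genes on them lay 0.391 to 0.419 above the mean of the wild type and Sox4 arrays in each K/L array, where the other 6 arrays lay at -0.009 to 0.029. Scaling of the K/L arrays is argued against by the other chromosomes, whose largest median in K/L versus Sox4 was 0.077 in size over genes with a mean log2 value above 7 (-0.113 to 0.185 in K/L versus wild type), and dim genes by a K/L versus Sox4 median of 0.353 over genes with a mean log2 value above 9 against 0.293 over all tested genes. Extra copies of both chromosomes in the K/L cells may account for the shift, as 96.4 percent of blocks of 40 neighbouring genes had a median above 0.1 between the leukaemias. The shift is smaller than the 0.58 that 3 copies over 2 give in RNA without compensation, and DNA is not analysed here. It was alike in all 3 K/L arrays, which may not come from separate leukaemias. The p-values of both K/L comparisons therefore measure the spread between arrays, which need not be that between leukaemias.

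Neighbouring genes elsewhere moved together too. The largest window of 15 neighbours between the leukaemias, on chromosome 13 from Slc38a9 to 4833420G17Rik and holding Emb, had a median of -0.908, with 15 of 15 genes lower in K/L cells, beyond the largest of 100 shuffled gene orders (0.6). On chromosome 2 the window from Slco4a1 to Prpf6 had a median of 0.655, and in K/L versus wild type that from Pcif1 to B4galt5 had 1.329 against a shuffled 0.975. That last window was also raised in Sox4 versus wild type (0.631), where the shuffled range was wider (1.358), and differed by 0.395 between the leukaemias. Against wild type, the chromosome 13 window and that from Slco4a1 had medians of -0.861 and 0.466 in K/L cells, within the shuffled 0.975. In Sox4 cells they had -0.093 and -0.024. A loss or gain of DNA segments in the K/L cells may be behind the windows that differ between the leukaemias, but neither passed against wild type. Expression shared by neighbours for other reasons remains open.

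Sox4 probe sets differed in both leukaemias. Changes from wild type over the 6 probe sets above the floor spanned 6.85 log2 units in K/L and 6.75 log2 units in Sox4 cells. These ranges restate the disagreement and by themselves exclude nothing. The labels name Sox4 overexpression for the Sox4 cells alone, yet the same 3 probe sets rose in K/L cells, by 6.8, 4.29 and 3.71. As far as the labels tell, this argues against an introduced copy lacking the part read by some probe sets as the cause in K/L cells. In Sox4 cells such a copy stays open. The 3 probe sets that did not rise may read other transcripts, and their residuals correlated with those of the risen probe sets at -0.17 on average. Those that did not rise correlated among themselves at 0.88, which probe sets reading the same transcript would show whether it is Sox4 or another. The risen ones correlated among themselves at 0.03, so the test could not decide, and no biological explanation was tested.

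Large falls from wild type were shared by both leukaemias, with 55 genes at least 8-fold lower in each, among them Ces1d and Hao1, which are known from liver. Cells of those tissues in the wild type sort are argued against by marker lists, whose medians in wild type arrays were 4.92 for liver, 4.88 for skeletal muscle, 4.72 for stroma, 4.46 for endothelium and 4.64 for kidney tubule, below the 60th percentile of 6.37, which 2 endothelial and 1 muscle marker exceeded. The gate for c-Kit would remove those without that receptor. The brightest markers were Apoa2 at 6.15, Mylpf at 6.67, Dcn at 5.23, Pecam1 at 10.26, which blood cells also express, and Slc22a6 at 5.67. Single faulty probe sets are argued against by a second probe set that also fell by over 1 log2 unit in 27 of 31 such genes with several probe sets, or 87.1 percent. The largest fall among a gene's other probe sets counted here. The rest of the 55 genes, Hao1 among them, have a single probe set and could not be tested in this way. A difference between normal and leukaemic cells, or between the mice they came from, may therefore lie behind these falls and stays untested.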
